A study of Homo sapiens with 4 samples.

How the data were processed

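The analysis used 4 RNA sequencing libraries of HEK293A cells, 2 labelled negative control and 2 labelled NT1_hp2. Per the labels' protocols, 300000 cells per well were seeded 24 h before transfection, FEN1 plasmid (1 µg) was followed after 48 h by DNA probes (500 pmol), total RNA was prepared after 72 h, and 1 µg of RNA entered a NEBNext Ultra RNA library kit. That kit does not mark strand, so reads of overlapping genes on opposite strands cannot be separated. Groups and replicate numbers were taken from the sample titles.

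The authors deposited 1 file per library with a value for each gene. The deposited values were taken as FPKM (reads scaled to gene length and library size), a unit inferred from the values because the file headers name only the gene and the library. The submitters' processing notes name the genome build GRCh38.p12, and the aligner, counter and normalization are not given in the sources used here. Each file listed 58736 features, of which 58735 were Ensembl gene identifiers found in GENCODE release 29 and 1 was named EGFP, and 58207 identifiers had a gene symbol. Multiplied by the summed exon length of the gene in GENCODE 29, 100% of the values above 0 in each library were whole multiples of a common step within 0.01, which gave the number of reads behind each value. The length of EGFP, 720 bases, was the shortest that gave whole reads. Recovered totals were 12558145 to 14973759 reads per library. The library size implied by the step was 0.962 to 1.04 times that total, so the values carry a scaling beyond plain totals.

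No 2 files were identical (0 pairs). The chi-square per degree of freedom of recovered reads was 2.78 for the NT1_hp2 pair and 6.30 for the negative control pair, so both pairs differed by more than sampling noise, and it was 15.7 to 33.9 between groups. Each library was therefore counted as 1 replicate.

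The design fixed before the data were examined asked for a count test if the files held counts and for limma-trend if they held normalized values. Because the deposited values are FPKM, the count test was not used. Genes with at least 1 FPKM in at least 2 libraries were kept, values were transformed as log2(FPKM + 1), which understates the change of genes at low levels, and the groups were compared with limma 3.58.1 (moderated statistics with an intensity trend and robust variance shrinkage) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all tested genes and called below 0.05. Standard errors of log2 fold changes are those of the moderated fit, and means ± SD of FPKM are over the 2 libraries of a group. Standard errors of list medians come from resampling the members of a list, so they measure spread between genes and not between libraries.

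Gene lists were written before the data were examined, 28 in all, of which 23 had at least 5 tested members. They cover FEN1 and flap processing, DNA repair, the p53 response, apoptosis, innate sensing, interferon, NF-kB, stress responses, cell cycle, metabolism, ribosome, respiratory chain, splicing, matrix and markers of other cell types. Lists were compared with all other tested genes by camera in limma, with a preset inter-gene correlation of 0.01 and with an estimated correlation. The rotation test fry, also in limma, tested only whether a list's own genes changed. It makes no comparison with other genes, so a shift shared by most genes can make a list pass. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries and not from the genes, so it has little power here. Adjustment was over the 23 lists. Counts adjusted over the list alone repeat the gene test's adjustment within each list.

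Genes were named by a rule fixed before the data were examined. It takes the 12 largest changes in each direction among genes that passed the test, had a symbol, a mean of at least 5 FPKM and both libraries of a group above both of the other, then FEN1, and up to 4 members with the smallest p-value in each list that passed or held a changed gene, with 2 members of the FEN1, p53 and interferon lists in any case. Further members given with their values, the EGFP row and the families in the closing section were chosen after values were seen. Some genes that the rule names are not reported here.

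Alternatives fixed beforehand were median-of-ratios, upper-quartile and total-based scaling, limma-voom on recovered reads, no robust shrinkage, no filter, at least 1 CPM in all 4 libraries, protein-coding genes only, a pseudocount of 0.1, a 2-fold minimum and omission of each library. Added after seeing the data were the removal of smooth per-library trends with transcript length and GC content (mgcv 1.9.3), using principal transcripts or deposited exon lengths, a minimum length of 300 bases, and omission of mitochondrially encoded genes. The principal-transcript correction tests only 12148 genes, so its counts compare with those for protein-coding genes alone and not with the main counts. Intervals of read ratios are exact binomial intervals scaled by library size and cover counting error only.

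The procedure was tested on simulated libraries drawn with the observed means and library sizes for the 16362 tested genes, and with 1 mean dispersion of 0.00617 for all of them. Genes were drawn independently and without a GC trend. The simulations therefore cannot show how the gene calls, the list test or the GC part of the correction behave with correlated genes or a GC trend. With 200 genes changed, 23.9% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 92.4% of those changed 4-fold were called in the right direction. Over 20 draws the mean share of unchanged genes among the calls was 12.5%, with a maximum of 17.3%. With no gene changed, 1 gene was called. A list raised by 0.4 on the log2 scale was called alone. A simulated length trend gave 60 calls before and 3 after the correction. File reading and figures used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.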

Results

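RNA levels were profiled by RNA sequencing in HEK293A cells, an established human embryonic kidney epithelial line. The study asked how genes are regulated by FEN1, a flap endonuclease of DNA replication and repair, when it is directed by hairpin-forming DNA probes. Per the labels' protocols, each well received 1 µg of FEN1 plasmid and, 48 h later, 500 pmol of DNA probes. The 4 libraries fell into 2 groups of 2, a negative control (replicates 1 and 3) and cells given the probe named NT1_hp2 (replicates 2 and 3). The gene that NT1_hp2 was designed against, and the probe used in the negative control, are not given in the sources used here, so no intended target was tested. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

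The deposited FPKM values corresponded to 14973759 and 12558145 reads in negative control replicates 1 and 3, and to 13695552 and 13649288 reads in NT1_hp2 replicates 2 and 3. For a gene of 1 kilobase, 3 reads amounted to 0.208 to 0.239 FPKM, and this floor covers counting error only. Mitochondrial transcripts took 6.03% and 5.89% of the reads in the negative control and 4.32% and 4.28% in NT1_hp2. Libraries of the same group resembled each other more than libraries of different groups. Across genes, Pearson's r of log2(FPKM + 1) was 0.972 within the negative control, 0.973 within NT1_hp2, and 0.944 to 0.960 between the groups. The first principal component held 58.2% of the variance and separated the groups, with negative control replicate 1 at −33.1 and replicate 3 at −16.3, and NT1_hp2 replicates 2 and 3 at 27.5 and 21.9.

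Cells given NT1_hp2 held more mRNA of genes of the ATF4 and amino acid response than the negative control, with 14 of 26 higher. ATF3, a stress-induced transcription factor, rose 2.67-fold, DDIT3, which encodes the stress factor CHOP, rose 2.29-fold, and the pseudokinase gene TRIB3 rose 2.11-fold. The immediate early genes FOS and EGR1, which encode growth factor-responsive transcription factors, fell to 0.124 and 0.146 of their control levels. Of the 13 mitochondrially encoded mRNAs 12 fell, and mRNAs of heat shock proteins, ribosomal proteins, histones and mitosis genes were lower as groups in camera with a preset correlation. With an estimated correlation 0 of 23 lists passed (smallest camera adjusted p = 0.782), in a test with little power for 4 libraries. Of 16362 genes tested, 818 rose and 1460 fell (limma-trend on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were fewer, with 99 genes higher and 76 lower.

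In all 2278 changed genes, both libraries of a group lay above both of the other, as did 66.8% of all tested genes, where chance gives 33.3%. The split between directions followed the scaling. It was 35.9% higher as deposited, 53.8% (1549 higher, 1328 lower) when libraries were scaled to their totals and 49.5% (1401 higher, 1430 lower) with upper-quartile factors. Among protein-coding genes alone it was 37.7% (1778 higher, 2938 lower) as deposited. In the 12148 genes with a principal transcript it was 45.7% (1267 higher, 1503 lower) after removal of trends with length and GC content. With deposited lengths in that correction, 556 genes passed (271 higher, 285 lower). With limma-trend, 0 genes passed without negative control replicate 1, negative control replicate 3 or NT1_hp2 replicate 2, 1 passed without NT1_hp2 replicate 3, and 0 passed without the filter, while 4220, 5836, 3315, 4158 and 6778 genes had an unadjusted p under 0.05.

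Among the 12 largest increases, ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777, GRCh38) went from 25.2 ± 0.816 to 67.3 ± 4.86 FPKM (mean ± SD, n = 2), a log2 fold change of 1.38 (SE 0.078, limma-trend adjusted p = 0.0340). DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737) went from 35.5 ± 1.48 to 81.5 ± 0.461 FPKM, and its exons overlap those of the genes MARS and MBD6 on the other strand. TRIB3 (chromosome 20, 362835 to 397559) went from 18.2 ± 2.996 to 38.4 ± 1.28 FPKM. ANKRD1, which encodes a cardiac and stress-induced ankyrin repeat protein, rose from 3.16 ± 0.304 to 8.10 ± 0.323 FPKM, and C11orf96 from 2.91 ± 0.308 to 8.03 ± 0.493 FPKM. The ribosomal protein pseudogene RPL17P50 (chromosome 10, 73005833 to 73006595) rose from 4.17 ± 0.944 to 9.05 ± 0.515 FPKM. It lies on the same strand just past the 3' end of P4HA1 (73007217 to 73096974), a far more abundant gene that also rose. Whether reads of RPL17P50 come from P4HA1 transcripts was not tested. The remaining 6 were RNU7-75P, MIR6746, a Y_RNA copy on the X chromosome, ALG13-AS1, BRCA1P1 and MIR186, all short annotated features inside introns of NUP155, FADS3, COL4A5, ALG13, BRCA1 and ZRANB2. These rested on few reads. RNU7-75P had 22 reads in NT1_hp2 against 4 in the negative control, a ratio of 5.24 (95% exact binomial interval 1.78 to 20.9), and MIR6746 had 18 against 4, a ratio of 4.28 (1.41 to 17.4).

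Of the 12 largest decreases, 8 were mitochondrial tRNA genes and another was MT-ATP8. It encodes a small subunit of the mitochondrial ATP synthase, and its exon overlaps MT-ATP6. MT-ATP8 had 41 reads in NT1_hp2 against 176 in the negative control, a ratio of 0.222 (95% exact binomial interval 0.154 to 0.313). MT-ATP6 had a smaller decrease that did not pass. How reads were divided between them is not given, so the value does not show a fall of MT-ATP8 apart from MT-ATP6. MT-TY went from 256 ± 27.1 to 39.6 ± 0.147 FPKM and MT-TC from 844 ± 21.3 to 151 ± 42.6 FPKM, with 1 base shared between these 2 tRNA genes. MT-TN fell from 445 ± 1.84 to 107 ± 42.7 FPKM, and MT-TH, MT-TV, MT-TS2, MT-TF and MT-TL2 fell with log2 fold changes of −2.82, −2.07, −2.99, −2.35 and −4.16. For MT-TL2 this came from 2 reads in NT1_hp2 against 58 in the negative control, a ratio of 0.0328 (95% exact binomial interval 0.00388 to 0.124). FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) went from 32.5 ± 9.93 to 4.02 ± 0.524 FPKM, and EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) from 42.4 ± 11.2 to 6.19 ± 0.278 FPKM, with log2 fold changes of −2.71 (SE 0.22) and −2.57 (SE 0.19). RN7SL2, a signal recognition particle RNA with near-identical copies in the genome, fell from 34.1 ± 8.43 to 5.88 ± 2.97 FPKM, and reads shared with those copies leave its level uncertain.

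**Figure D1:**
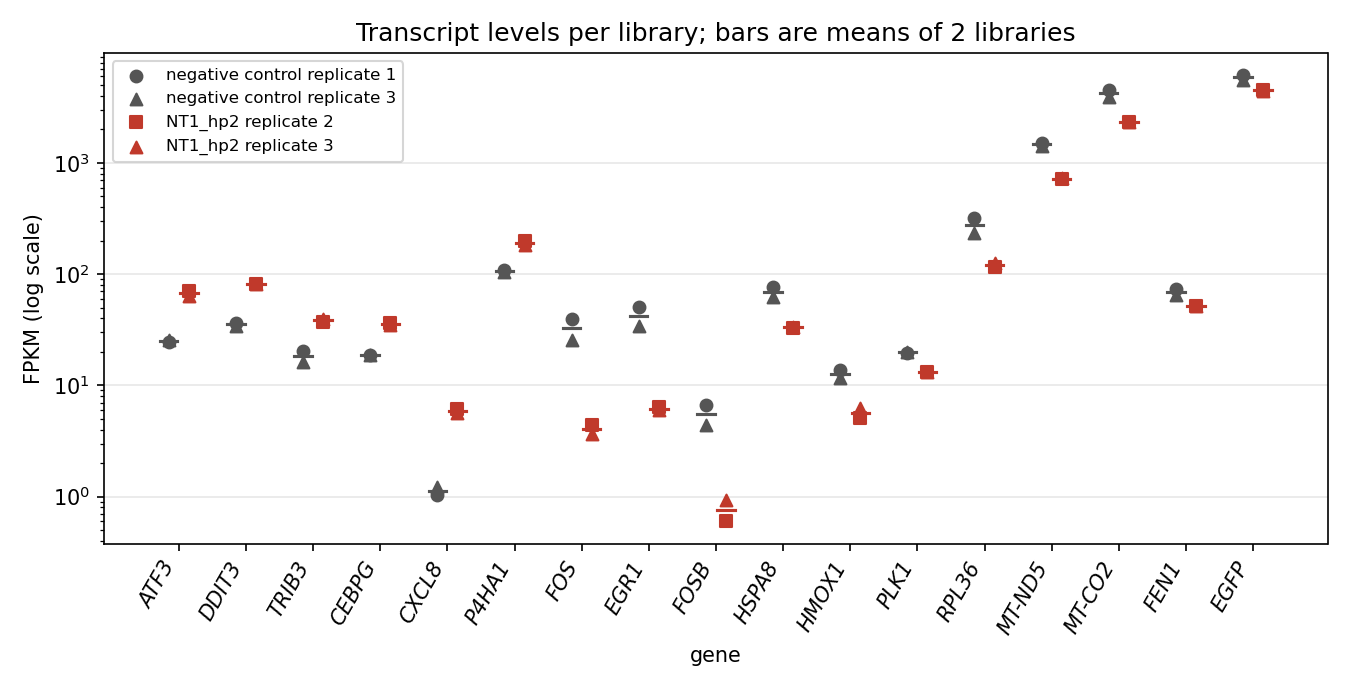
FPKM on a log axis for 17 transcripts in the 4 libraries, grey for negative control and red for NT1_hp2, with symbols marking the replicate number and bars the mean of the 2 libraries. ATF3 lies at 24.6 and 25.8 FPKM in the negative control and at 70.7 and 63.9 in NT1_hp2, while EGFP did not pass the test.

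FEN1, the nuclease supplied on a plasmid in every well, was measured at 69.1 ± 6.48 FPKM in the negative control and 51.4 ± 0.111 in NT1_hp2 (n = 2 each). The difference was −0.42 on the log2(FPKM + 1) scale (SE 0.086, limma-trend adjusted p = 0.0441). FEN1 (chromosome 11, 61792637 to 61797244) ranked 469th by mean FPKM of the 58736 listed features and 2nd among the 30 tested members of its list, and its exons overlap FADS2 and TMEM258. The sources used here do not say whether the plasmid carries the human sequence, so the reads may or may not include plasmid-derived transcripts. A row named EGFP, chosen after its values were seen, was the 5th most abundant, at 5879 ± 373 FPKM in the negative control and 4507 ± 99.6 in NT1_hp2, a log2 difference of −0.38 (SE 0.092, limma-trend adjusted p = 0.0559) that did not pass, although it passed with upper-quartile factors (0.0357), library totals (0.0320), limma-voom (4.0e-05), at least 1 CPM (0.0327) and genes of at least 300 bases (0.0380). Whether EGFP was on the FEN1 plasmid, a reporter in the cells or the target of NT1_hp2 is not given. Of 47 nuclear mRNAs of 500 to 1000 bases with a mean of at least 100 FPKM, 23 were as low or lower than EGFP in NT1_hp2 relative to control. FEN1 was not past the threshold without any 1 of the libraries, but almost no gene was in those fits, so this does not single out FEN1. Its log2 difference was −0.32 without negative control replicate 1, −0.51 without negative control replicate 3, and −0.42 without NT1_hp2 replicate 2 or 3. After the length and GC correction it was at −0.26 with principal transcripts and at −0.19 with deposited lengths, the latter without passing (adjusted p = 0.0779, limma-trend). The 2 genes of the list of FEN1 and its lagging-strand partners that changed were FEN1 and the single-strand break repair scaffold gene XRCC1, which went from 11.4 ± 1.53 to 6.79 ± 0.971 FPKM. The exonuclease gene EXO1 (log2 fold change 0.40) and the helicase gene BLM (0.26) did not pass. Adjusted over the list alone, 0 of the 30 members passed, and the list itself had a camera adjusted p of 0.704. Its members went 5 higher and 2 lower with library totals, 4 and 2 with upper-quartile factors, 5 and 3 after the principal-transcript correction, and 0 and 0 with deposited lengths.

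Of 23 gene lists large enough to test, 9 passed camera with a preset correlation of 0.01, 3 higher and 6 lower in NT1_hp2. With an estimated correlation 0 passed, with a smallest camera adjusted p of 0.782. That version takes its degrees of freedom from the 4 libraries and not from the genes, so it has little power here. The histone list had an estimated correlation of −0.016, below the preset one, yet its unadjusted camera p went from 0.000488 to 0.0657. Failure to pass it therefore does not show that correlation between genes accounts for a result. The rotation test fry asks whether a list's genes move on balance in a common direction, without comparison with other genes. In it 3 passed, for innate nucleic acid sensors (fry adjusted p = 0.0200), histones (0.0266) and ATF4 targets (0.0304).

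Genes of the ATF4 and amino acid starvation response rose together, with 14 of 26 tested members higher and 0 lower (15 and 0 adjusted over the list alone) and a median log2 fold change of 0.48. The increase reached the transcription factor CEBPG (18.8 ± 0.0752 to 35.7 ± 0.925 FPKM), the cystine transporter SLC7A11 (2.11 ± 0.0668 to 5.36 ± 0.346), the mitochondrial folate enzyme ALDH1L2 (3.88 ± 0.0464 to 7.61 ± 0.146) and DDIT3. Asparagine synthetase ASNS (log2 fold change 0.82), the serine synthesis enzyme PSAT1 (0.66) and the folate enzyme MTHFD2 (0.85) also rose. The mRNA of ATF4 itself did not pass (171 ± 19.5 to 145 ± 1.67 FPKM, −0.23), nor did CHAC1 (−0.06), PHGDH (0.08) or SHMT2 (0.08). The list passed camera with an adjusted p of 2.8e-08, against an adjusted p of 0.782 with an estimated correlation.

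Stress genes of other kinds moved in different directions. Of 22 endoplasmic reticulum chaperone and XBP1/ATF6 target genes, 7 rose and 1 fell (9 and 3 adjusted over the list alone). XBP1, a transcription factor of the unfolded protein response, went from 45.4 ± 0.393 to 65.6 ± 2.93 FPKM, the sensor ERN1 from 3.61 ± 0.0531 to 5.65 ± 0.181, and the co-chaperone DNAJB9 from 7.13 ± 0.0900 to 11.7 ± 0.501, while SDF2L1 fell from 19.7 ± 1.54 to 11.4 ± 0.457. The list had a camera adjusted p of 0.175 (0.785 with an estimated correlation), and it passed after the principal-transcript correction (0.0112) but not with deposited lengths (0.0612). Cytosolic heat shock genes fell, 7 of 18 with 0 higher (13 lower and 2 higher adjusted over the list alone), with a median of −0.32 (camera adjusted p = 0.000294, and 0.782 as the adjusted p with an estimated correlation). The chaperone HSPA8 fell from 69.6 ± 10.4 to 33.2 ± 0.906 FPKM, HSPA1B from 51.5 ± 1.997 to 26.02 ± 3.27, and the small heat shock protein gene HSPB1 from 112 ± 10.2 to 65.0 ± 0.364. HSPA1B shares most of its sequence with HSPA1A, which was at −0.76 without passing, so the division of reads between them is uncertain. HMOX1, heme oxygenase, fell from 12.7 ± 1.41 to 5.68 ± 0.789 FPKM. It also belongs to the NRF2 target list, of which 2 rose (SLC7A11 and ME1) and 5 fell among 15 (2 and 8 adjusted over the list alone), with a camera adjusted p of 0.175, or 0.0410 without the filter, 0.0413 after the deposited-length correction and 0.134 after the principal-transcript correction, against 0.785 with an estimated correlation.

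Hypoxia and glycolysis genes included 7 that rose and 2 that fell among 28 (9 and 4 adjusted over the list alone). The collagen prolyl hydroxylase P4HA1 went from 106 ± 3.54 to 191 ± 10.0 FPKM, the hexokinase HK2 from 10.6 ± 0.0961 to 16.8 ± 0.0790, and NDRG1 from 80.7 ± 1.57 to 117 ± 2.28, while MXI1 rose by 0.51 on the log2 scale and the glycolytic enzyme gene TPI1 changed by −0.57. The camera adjusted p was 0.0660, and 0.785 with an estimated correlation. With the preset correlation the list passed under several other settings, at 0.0336 with library totals, 0.0157 with limma-voom, 0.0168 without negative control replicate 1, and 3.5e-06 and 0.000116 after the corrections with principal transcripts and deposited lengths. It did not pass at 0.325 without negative control replicate 3, 0.119 without the filter or 0.0747 without NT1_hp2 replicate 3.

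NF-kB target and cytokine genes passed as a list (median 0.27, camera adjusted p = 0.0195, and 0.782 as the adjusted p with an estimated correlation), with 3 higher and 1 lower of 16 (8 and 1 adjusted over the list alone). The chemokine gene CXCL8 rose from 1.13 ± 0.132 to 5.89 ± 0.351 FPKM, the ubiquitin-editing enzyme TNFAIP3 from 2.68 ± 0.0498 to 4.79 ± 0.265, and RELB from 3.41 ± 0.294 to 5.66 ± 0.522, and TNFAIP2 fell from 16.4 ± 0.307 to 11.9 ± 0.541. Without negative control replicate 3 the list did not pass (camera adjusted p = 0.106). Its median was 0.12 with at least 1 CPM in all 4 libraries and 0.43 after the principal-transcript correction. No member of the innate nucleic acid sensor or interferon-stimulated lists rose with limma-trend over all tested genes, but with limma-voom 1 member of each list was higher. Among protein-coding genes alone 1 interferon-stimulated gene was higher and 6 lower, and among genes of at least 300 bases 1 was higher and 3 lower. After the principal-transcript correction 4 interferon-stimulated genes were higher and 4 lower, and with deposited lengths 0 members of either list changed. STING1, the adaptor of cytosolic DNA sensing, fell from 13.3 ± 0.805 to 8.59 ± 0.422 FPKM, the transcription factor IRF3 from 15.3 ± 1.38 to 10.2 ± 0.344 and DDX41 from 13.4 ± 1.26 to 8.81 ± 0.737, making 3 of 11 sensors lower (3 lower and 0 higher adjusted over the list alone, camera adjusted p = 0.255), and TICAM1 was at −0.34 without passing. Of 24 interferon-stimulated genes 3 fell (2 adjusted over the list alone), IFI6 at −0.74, IFITM1 at −0.65 and IFI35 at −0.33, the last at 0.019 after the length and GC correction with deposited lengths, whereas IFIT1 was at −0.37 without passing (camera adjusted p = 0.506).

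Immediate early genes went both ways. FOSB fell from 5.51 ± 1.59 to 0.763 ± 0.231 FPKM alongside FOS and EGR1, and ATF3 and KLF6 rose, so that 2 of 20 were higher and 6 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.255). After the principal-transcript correction 6 were higher and 5 lower, and with deposited lengths 3 and 4. Of 24 p53 targets 1 rose and 7 fell (3 and 10 adjusted over the list alone, camera adjusted p = 0.291). These numbers were 5 and 6 with library totals, 4 and 7 with upper-quartile factors, 4 and 8 after the principal-transcript correction, and 3 and 2 with deposited lengths. The apoptosis effector BAX fell from 46.2 ± 6.22 to 26.3 ± 2.43 FPKM, PHLDA3 from 18.1 ± 2.65 to 10.0 ± 0.165, FDXR from 23.2 ± 1.66 to 15.2 ± 1.06 and TP53I3 from 2.81 ± 0.0207 to 1.15 ± 0.104, and MDM2 did not pass at 0.05. Of 22 apoptosis regulators 1 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.862), with the inhibitor XIAP at 0.33 and BMF, BAX and BCL2L1 at −0.72, −0.79 and −0.71. For this list 4 were higher and 4 lower with library totals and with upper-quartile factors. It had 2 higher and 4 lower after the principal-transcript correction, and 0 and 2 with deposited lengths.

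All 13 mitochondrially encoded mRNAs had lower means in NT1_hp2, and 12 fell (13 adjusted over the list alone), with a median of −0.66. MT-ND5, a subunit of respiratory complex I, went from 1469 ± 55.1 to 725 ± 8.30 FPKM, MT-ND1 from 1699 ± 85.2 to 868 ± 56.0, MT-ND6 from 1484 ± 95.2 to 761 ± 30.3 and the cytochrome oxidase subunit MT-CO2 from 4222 ± 447 to 2334 ± 21.1. MT-ATP6 was the exception at −0.39 (limma-trend adjusted p = 0.0629), and its exon overlaps that of MT-ATP8, so their values may not be separate. Camera gave an adjusted p of 4.1e-07, and the adjusted p was 0.782 with an estimated correlation. Nuclear-encoded respiratory chain subunits fell in 14 of 60 cases with 0 higher (19 lower and 1 higher adjusted over the list alone), with a median of −0.26, for example NDUFB7 (96.7 ± 15.7 to 44.4 ± 6.61 FPKM), COX6B1 (122 ± 19.8 to 65.6 ± 1.78), UQCR10 at −0.86 and NDUFS6 at −0.73. Their median was −0.16 without negative control replicate 1, and −0.12 after the principal-transcript correction with 4 higher and 19 lower. Among protein-coding genes alone, without correction, 1 respiratory chain gene was higher and 30 were lower. Cytosolic ribosomal protein genes fell in 18 of 76 cases with 0 higher (28 and 0 adjusted over the list alone), with a median of −0.28, among them RPL8 (837 ± 100 to 460 ± 13.7 FPKM), RPL36 (277 ± 58.1 to 121 ± 7.29), RPL11 at −0.84 and RPL37 at −0.60, and many processed pseudogenes can take reads from these genes. The ribosomal protein median was −0.17 without negative control replicate 1, and −0.13 after the principal-transcript correction with 7 higher and 33 lower. Among protein-coding genes alone, without correction, 1 ribosomal protein gene was higher and 42 were lower. Camera gave adjusted p-values of 1.7e-05 for the respiratory chain and 2.8e-08 for the ribosomal proteins, against adjusted p-values of 0.785 for both with an estimated correlation.

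Replication-dependent histone genes fell in 5 of 14 cases with 0 higher (8 and 0 adjusted over the list alone), with a median of −0.42 (camera adjusted p = 0.00187, and 0.782 as the adjusted p with an estimated correlation). Their mRNAs lack poly(A) tails, and only 14 of the 42 listed genes reached the level needed for testing. The linker histone gene H1-2 went from 94.3 ± 5.14 to 52.8 ± 3.38 FPKM and H2BC12 from 133 ± 18.8 to 62.5 ± 2.07, while H2BC11 and H2AC6 were at −0.62 and −0.58. Mitosis genes fell in 7 of 32 cases with 0 higher (9 and 0 adjusted over the list alone), with a median of −0.16 (camera adjusted p = 0.00773, and 0.782 as the adjusted p with an estimated correlation). The kinesin KIF20A fell from 21.6 ± 0.568 to 13.6 ± 0.0124 FPKM, the kinase PLK1 from 19.8 ± 0.287 to 13.2 ± 0.00713, the anaphase activator CDC20 from 58.5 ± 5.57 to 37.9 ± 2.41 and GTSE1 by 0.40 on the log2 scale. The list had a median of −0.08 with library totals, still past camera (adjusted p = 0.0334), and did not pass at −0.12 without NT1_hp2 replicate 3. After the principal-transcript correction its median was −0.20, with 0 higher and 16 lower (camera adjusted p = 3.3e-08). With deposited lengths it was −0.17, with 0 higher and 4 lower (6.3e-09). Of 28 DNA replication and G1/S genes 1 rose, the origin recognition gene ORC6 at 0.66, and 2 fell, the thymidylate synthase TYMS at −0.49 and the helicase subunit MCM5 at −0.47 (1 and 2 adjusted over the list alone, camera adjusted p = 0.903). MCM10 was at 0.28 without passing. The G1/S list had 3 higher and 2 lower with library totals and with upper-quartile factors, and 4 higher and 6 lower with limma-voom. After the principal-transcript correction 5 were higher and 3 lower, and with deposited lengths 2 and 1. Homologous recombination and Fanconi anaemia genes passed as a list with a median of 0.18 (camera adjusted p = 0.00874, and 0.782 as the adjusted p with an estimated correlation), with 4 higher and 1 lower of 29 (9 and 1 adjusted over the list alone). BRCA1 rose from 10.97 ± 0.788 to 14.8 ± 0.452 FPKM, BRIP1 from 9.90 ± 0.795 to 13.7 ± 1.10 and RBBP8 from 8.59 ± 0.569 to 11.5 ± 0.0454, while FANCG fell from 16.2 ± 0.548 to 11.05 ± 0.691. After removal of length and GC trends the list had a median of 0.07 and did not pass (camera adjusted p = 0.145).

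**Figure D2:**
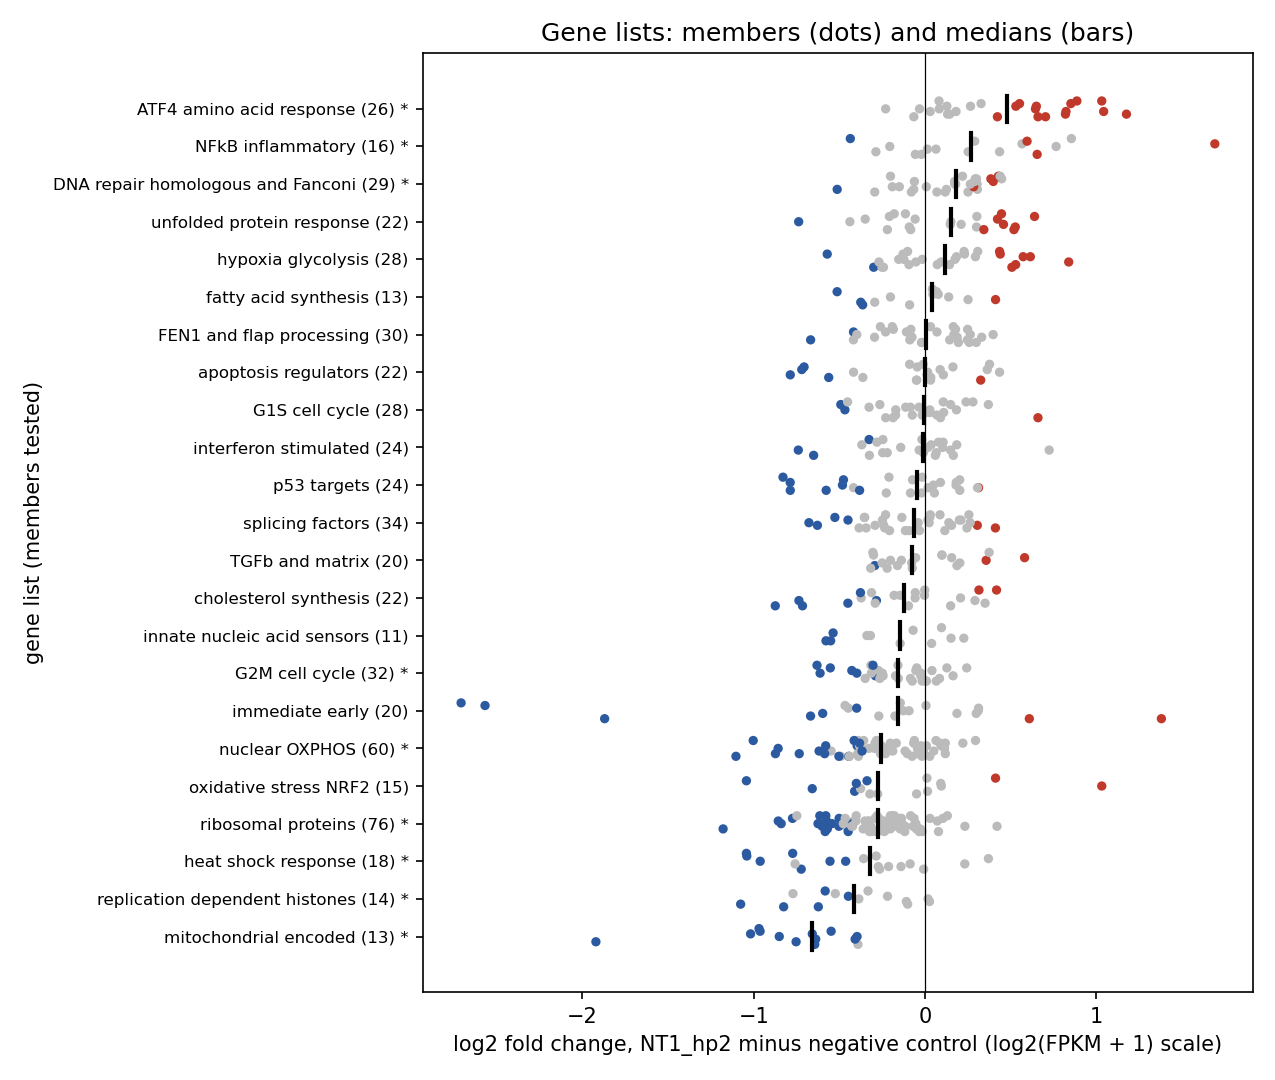
Log2 fold change of NT1_hp2 minus negative control for the members (dots) of the 23 tested gene lists, with medians as black bars, red and blue dots for members that rose or fell, and an asterisk where camera passed with the preset correlation. The ATF4 list has the highest median at 0.48 and the mitochondrially encoded mRNAs the lowest at −0.66.

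Metabolic and structural lists did not pass camera with values as deposited or had too few members for it. Of 22 cholesterol synthesis and uptake genes 2 rose and 6 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.192, or 0.0256 without the filter and 0.785 with an estimated correlation), with MVD, TM7SF2 and NSDHL at −0.71, −0.87 and −0.74. Of 13 fatty acid synthesis genes 1 rose, the malic enzyme ME1 at 0.41, and 3 fell, FASN at −0.37, SREBF1 at −0.51 and FADS2, which overlaps FEN1, at −0.36 (2 and 4 adjusted over the list alone, camera adjusted p = 0.821, with a median of 0.04 and a mean of −0.06). FASN, SREBF1 and FADS2 have 65.3%, 64.7% and 60.7% GC, and all genes of at least 60% GC had a median of −0.31. The fatty acid list had 1 higher and 1 lower after the principal-transcript correction, and 0 and 0 with deposited lengths. Of 34 splicing factor genes 2 rose and 4 fell (6 and 12 adjusted over the list alone, camera adjusted p = 0.431), among them the kinase CLK1 at 0.41 and HNRNPA1, HNRNPM and HNRNPA2B1 at −0.68, −0.63 and −0.45. This list passed as lower after the corrections, with principal transcripts (camera adjusted p = 0.0199, 5 higher and 15 lower) and with deposited lengths (6.3e-05, median −0.20), whereas 7 were higher and 5 lower with library totals (median 0.01, camera adjusted p = 0.681). The adjusted p with an estimated correlation, for values as deposited, was 0.842. Of 20 TGF-beta and matrix genes the collagen crosslinker LOX rose from 9.75 ± 0.229 to 15.1 ± 0.497 FPKM and fibronectin FN1 from 52.4 ± 1.47 to 67.3 ± 0.392, and COL6A1 fell by 0.29 on the log2 scale, or was at 0.013 after the length and GC correction with deposited lengths, with COL5A1 at −0.30 without passing (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.758). The metallothionein list had 4 tested members, too few for camera. MT2A fell from 47.9 ± 3.35 to 27.6 ± 2.43 FPKM, and MT1X, MT1F and SLC30A1 were at −0.49, −0.33 and 0.08 without passing (2 lower adjusted over the list alone).

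Markers of other cell types were scarce in both groups. None of 12 hepatocyte markers reached the level needed for testing, and of 10 fibroblast markers and 16 blood and immune markers, 3 and 2 were tested and 0 passed. COL1A1 and LUM of the fibroblast list were at −0.08 and 0.15, and CORO1A of the blood list at −0.34. Of 12 markers of keratin-rich carcinoma epithelium 4 were tested. KRT17 rose from 7.70 ± 0.590 to 12.7 ± 0.941 FPKM, and KRT19, S100A2 and GREB1 were at −0.29, −0.38 and 0.14 without passing (1 higher and 1 lower adjusted over the list alone).

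Fold changes followed the GC content and length of transcripts. The 1775 nuclear protein-coding genes under 40% GC had a median log2 fold change of 0.22, with 302 higher and 9 lower, and the 2070 of at least 60% GC had −0.31, with 8 higher and 608 lower. Across 12127 genes, which are not independent replicates, Spearman's rho of fold change was −0.656 with GC content and 0.361 with length. Between the 2 negative control libraries (replicate 3 minus 1) rho was −0.316 and 0.417, and between the 2 NT1_hp2 libraries (replicate 3 minus 2) it was 0.348 and −0.03. Ribosomal protein mRNAs had a median length of 1029 bases, nuclear respiratory chain mRNAs 1058.5 and histone mRNAs 771.5, against 3192.5 for all tested protein-coding genes. The homologous recombination list had a median GC content of 42.2% and the ATF4 list 53.1%, against 49.1% for all. In simulated libraries with 200 changed genes, 23.9% of 1.5-fold, 76.1% of 2-fold and 92.4% of 4-fold changes were called, and on average 12.5% of the calls were unchanged genes, above the nominal rate. These libraries held no GC or length trend and no correlation between genes, so error rates in the data may differ.

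**Figure D3:**
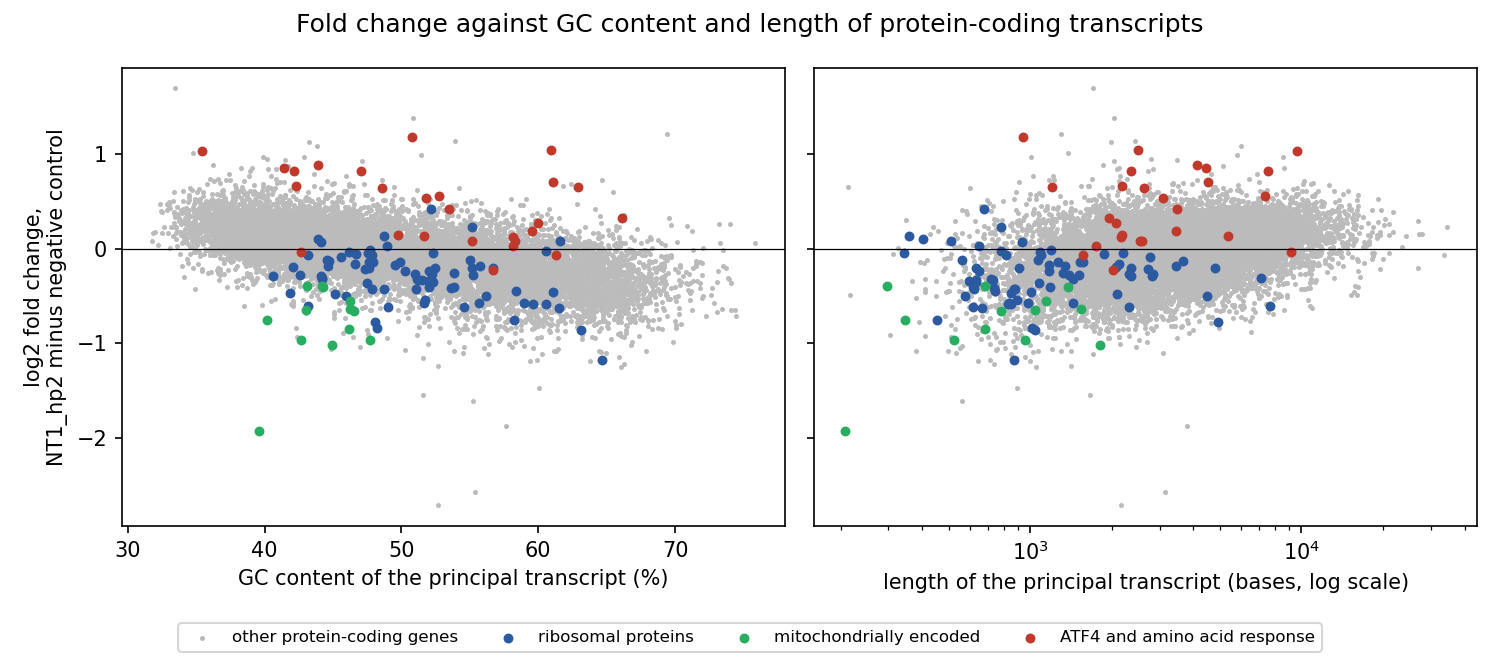
Log2 fold change of NT1_hp2 minus negative control against GC content in percent and length in bases (log axis) of the principal transcript, with 1 dot per protein-coding gene and ribosomal protein, mitochondrially encoded and ATF4 list members in colour. Medians run from 0.22 under 40% GC to −0.31 at 60% GC or more, and the ATF4 list members lie mostly above 0 on both panels.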

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

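No paired analysis was possible because the groups share only replicate number 3. The edgeR quasi-likelihood test was planned only for files that hold counts, and neither it nor a DESeq2 Wald test was run. Reads recovered from the deposited values were tested with limma-voom. The corrections for length and GC content, the 300-base minimum and the omission of mitochondrially encoded genes were chosen after seeing the data. With 2 libraries per group, each fit that omits 1 assumes that the lone library varies like the others. Where no cause is named below, the cause was not tested.

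The 2278 changed genes (818 higher, 1460 lower) stayed within 1.5 times that number with median-of-ratios, upper-quartile or total-based scaling, without robust shrinkage, with a pseudocount of 0.1, after the correction with principal transcripts and without mitochondrially encoded genes, although the higher genes numbered 1401 with upper-quartile factors, 1549 with library totals and 1267 after the principal-transcript correction. The numbers were 5619 (2361 higher, 3258 lower) with limma-voom, 4197 (1624, 2573) with at least 1 CPM in all 4 libraries, 4716 (1778, 2938) for protein-coding genes, 3585 (1349, 2236) for genes of at least 300 bases, 556 (271, 285) after the correction with deposited lengths and 175 (99, 76) with a 2-fold minimum, which by construction removes smaller changes. Without the filter 0 genes passed (0 higher, 0 lower), among 36608 tested and 6778 with an unadjusted p under 0.05, where limma-voom on the filtered genes called 5619. Leaving out each library gave 0 to 1 genes (0 higher, 0 to 1 lower), with 3315 to 5836 genes at an unadjusted p under 0.05. Of the main calls, 15 had the opposite sign after the principal-transcript correction and 23 after the deposited-length correction.

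Members of the lists that changed numbered 161, against 331 with limma-voom, 250 with at least 1 CPM, 308 for protein-coding genes, 264 and 95 after the principal-transcript and deposited-length corrections, 0 without the filter and 0 when any library was left out. Of the lists, 9 passed, 8 to 11 under the other settings, 0 with an estimated correlation and 3 with fry. The difference between the lowest correlation within a group and the highest between groups was 0.012, 0.0027 for limma-voom values, 0.0054 without the filter, 0.0061 with a pseudocount of 0.1, 0.0073 after the principal-transcript correction, and 0.012 to 0.023 when a library was left out.

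The log2 fold change of FEN1 was −0.42 (adjusted p = 0.0441, limma-trend). It was −0.42 without the filter (adjusted p = 0.143, more genes tested), −0.19 after the deposited-length correction (0.0779) and −0.51 to −0.32 when a library was left out (0.0606 to 0.231), and it passed under the other settings in which it was tested. Its change is below 2-fold, so it was not tested against the 2-fold minimum. EGFP, at −0.38 (adjusted p = 0.0559, limma-trend), passed at −0.32 with upper-quartile factors (0.0357), −0.30 with library totals (0.0320), −0.38 with limma-voom (4.0e-05), −0.38 with at least 1 CPM (0.0327) and −0.38 for genes of at least 300 bases (0.0380), its adjusted p ranging up to 0.362 when a library was left out. It has no GC content here and no corrected value.

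The sign reversed in 9 values of named genes, none past the threshold once reversed, although IFI35 and COL6A1 had passed before. After the principal-transcript correction MT1F was at 0.058, SLC30A1 at −0.15 and KRT19 at 0.069. After the deposited-length correction TICAM1 was at 0.026, IFI35 at 0.019, MT1F at 0.0080, SLC30A1 at −0.10, KRT19 at 0.078 and COL6A1 at 0.013. Camera's direction reversed for lists that passed neither before nor after, with these medians. The apoptosis list had 0.049 with upper-quartile factors, 0.063 with library totals and −0.046 to 0.028 when a library was left out (0.0085 without negative control replicate 1), and the fatty acid list 0.10 and 0.12 with those scalings. The G1/S list had 0.047 and 0.062 with those scalings, −0.0060 for protein-coding genes, 0.00063 and 0.038 after the principal-transcript and deposited-length corrections, and −0.051 to 0.040 when a library was left out (−0.00011 without negative control replicate 1 and 0.040 without NT1_hp2 replicate 3). The TGF-beta list had −0.076 for protein-coding genes and 0.070 and 0.080 after the 2 corrections, the immediate early list 0.036 and 0.018 after them, and the FEN1 list −0.033 to 0.055 when a library was left out, the lowest without negative control replicate 3. Of the other values for named genes and lists, 1610 kept their direction and side of the threshold, 582 no longer passed and 55 newly passed. Reads limit the intronic features and mitochondrial tRNAs, some of which had 0 reads in a group.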

Other observations

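The families described here were chosen after their values were seen. Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, rose in 11 of 20 cases and fell in 2, with a median log2 fold change of 0.35 that stayed above 0 under each scaling (0.35 to 0.43). The family shares at least AARS1 with the ATF4 list, so it is not independent of that result. MARS1, named MARS above, rose by 0.36 (limma-trend adjusted p = 0.0487). Its exons overlap those of DDIT3 on the other strand, so its reads may include those of DDIT3. IARS1 went from 34.7 ± 1.20 to 60.7 ± 1.79 FPKM, and GARS1, WARS1 and FARSB rose by 0.65, 0.53 and 0.46 on the log2 scale, whereas QARS1 (−0.62) and FARSA (−0.44) fell. After the principal-transcript and deposited-length corrections the family median was 0.25 and 0.26, with 9 higher and 1 lower under the latter, where FARSA was at −0.10. The tRNA export receptor XPOT rose from 27.1 to 45.9 FPKM. Of 16 mitochondrial aminoacyl-tRNA synthetase genes 0 rose and 1, VARS2, fell, with a median of −0.09, and the difference between the families was not tested.

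Values of mitochondrial tRNA genes fell in 15 of 21 cases and rose in 0, with a median of −2.07 (−2.07 to −1.996 under the other scalings), a median of 26.5 reads in the negative control, and MT-TI at 0.47 without passing. Those among the largest decreases span 59 to 73 bases. Whether their reads come from mature tRNAs or from longer RNAs was not tested, so the values do not measure mature tRNA levels. Of the mitochondrial rRNAs MT-RNR2 fell by 0.52 on the log2 scale and MT-RNR1 was at −0.17 without passing. Genes of mitochondrial ribosomal proteins fell in 17 of 76 cases and rose in 1 (median −0.25), and proteasome subunit genes fell in 8 of 40 and rose in 0 (median −0.21), with both medians below 0 under each scaling. After the principal-transcript and deposited-length corrections the mitochondrial ribosomal protein median was −0.15 and the proteasome medians were −0.11 and −0.19, with 4 and 2 genes lower under the deposited-length correction. Among 725 nuclear features under 200 bases that lie inside introns, 68 rose and 13 fell, with a median of 0.31 and a median of 2 reads in the negative control, and 23 rose and 4 fell after the deposited-length correction. The small Cajal body RNAs SCARNA8, SCARNA22 and SCARNA3 rose by 2.60, 1.46 and 1.58 on the log2 scale, and 0 of the 8 tested fell. The family had a median of 2 reads in the negative control, SCARNA8 had 0 there, and 2 of the 8 rose after the deposited-length correction.

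Of the tests below, those of a trend, a single library or the scaling as the whole cause were chosen only after the result was seen. The corrected values rest on the trend corrections, which were also added after seeing the data. Each SE of a median comes from resampling list members as if independent and leaves out the spread between libraries. Estimated correlations between members were 0.869 for mitochondrially encoded, 0.737 for ribosomal protein, 0.450 for respiratory chain and 0.168 for ATF4 genes. Each argument below therefore covers only the listed genes in these 4 libraries.

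Mitochondrially encoded mRNAs were lower in NT1_hp2, with a median of −0.66 (SE 0.11, 13 mRNAs). A trend with length and GC content is argued against, since the median was −0.6194 (SE 0.11) after the correction. A single library is argued against by a median of −0.598 (SE 0.099) without negative control replicate 1, the omission that brought it closest to 0, and the scaling by −0.5793 (SE 0.112) with library totals. A lower yield of mitochondrial RNA in the NT1_hp2 wells during extraction or library preparation was not tested and stays open, because labels give no preparation batch.

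Ribosomal protein and nuclear respiratory chain mRNAs were lower in NT1_hp2, with medians of −0.2771 (SE 0.0343, 76 mRNAs) and −0.2552 (SE 0.039, 60 mRNAs). After the length and GC correction they were −0.1291 (SE 0.0322) and −0.1225 (SE 0.0229), still past camera with the preset correlation, which argues against such a trend as the whole cause. With an estimated correlation neither list passed as deposited (camera adjusted p = 0.785 for both). Without negative control replicate 1 the ribosomal protein median was −0.1661 (SE 0.0297) and also past camera, which argues against that library as the whole cause. All of these medians lie between the bounds of −0.1 and −0.2 set beforehand, so a partial contribution of the trend or of that library cannot be told apart from a difference between the groups.

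ATF4 and amino acid response mRNAs were higher in NT1_hp2, with a median of 0.4767 (SE 0.16, 26 mRNAs). The length and GC correction left a median of 0.5926 (SE 0.0795), which argues against that trend. The median closest to 0 was 0.4366 (SE 0.17) when 1 library was left out, here NT1_hp2 replicate 2, and 0.4761 (SE 0.16) under another scaling, here median-of-ratios, both above 0 by more than 2 SE and past camera with the preset correlation, which argues against either as the whole cause. With an estimated correlation the list as deposited did not pass (camera adjusted p = 0.782). Neither the leave-out nor the median-of-ratios median exceeded the bound of 0.3 set beforehand by more than 2 SE. A partial contribution of a single library stays open. Median-of-ratios, upper-quartile and total-based scaling gave medians of 0.476, 0.535 and 0.552, against 0.477 as deposited. The increase therefore did not depend on the choice among these scalings. By the bound set beforehand, a partial contribution of the scaling cannot be told. A difference in handling or in transfection load between the wells was not tested.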
